A study of Homo sapiens with 3 samples.

How the data were processed

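The data are RNA sequencing profiles of HA1800 cells, human fetal cortical astrocytes sold for culture, taken at passages 10 to 15. Per the labels' protocols, total RNA was extracted with a column kit, polyadenylated RNA was enriched and libraries were made with a KAPA RNA kit. The 3 libraries form 1 group, numbered as replicates 1, 2 and 3 in the labels. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical. The series title concerns converting such astrocytes into neurons with chemicals that act on several signalling pathways. Libraries of treated or converted cells are not analysed here, and with 1 group no comparison between conditions was made.

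The submitters' processing notes name FastQC 0.11.3, HISAT2 2.0.4, StringTie 1.3.4 and the genome build hg19. FastQC reports on read quality, HISAT2 aligns reads across splice junctions and StringTie assembles transcripts and estimates their abundance. The options, the gene annotation and its version, read trimming and strand handling are not given in the sources used here. Each deposited table has 1 line per gene locus with its name, position and abundance. The tables hold 25258, 25253 and 25244 lines for replicates 1, 2 and 3, and the same 23710 gene names.

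Abundance is given in TPM, the share of all transcripts scaled to a fixed total, per the file headers, and the deposited TPM column sums to 1000000 in each library. The tables also give FPKM, fragments per kilobase scaled to sequencing depth, per the file headers, which differs from TPM by 1 constant per library. The deposited coverage column holds the mean read coverage of each gene, per the file headers. None of these is a count, so no count model was used and no p-value between libraries was computed.

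Depth is not stated in the tables. It was inferred from the median ratio of coverage to FPKM over lines with an FPKM above 1. Under the usual definition of both columns this gives 4.13, 4.76 and 4.14 Gb of aligned sequence for replicates 1, 2 and 3. For the lowest genes, coverage was multiplied by the listed span, introns included. The most frequent product was 50, seen in 54, 42 and 60 genes, and this was taken as the read length. The product equals the number of covered bases only in genes without introns, so the read length is an assumption. The implied depth was 82.6, 95.1 and 82.9 M reads. At that depth 1 read over a transcript of 1 kb is worth 0.0321, 0.0278 and 0.0319 TPM, so a gene at 1 TPM rests on about 31.1, 36.0 and 31.3 reads per kb. These are estimates that cover counting error only.

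Lines with the same gene name were summed within a library. This affected 512, 498 and 498 names. All 1269 lines on alternative haplotypes and unplaced sequences were at 0 in all 3 libraries, and the tables have 0 lines on the mitochondrial genome. Genes on the Y chromosome and the X-inactivation transcripts, 127 names in all, were left out, which left 23583. Gene types came from a current reference gene table (GRCh38) matched by name, with 22639 names matched and 18839 of them protein coding. No coordinates were taken from that build, and positions in the text are those of the deposited tables on hg19. An exact 0 can be a failed estimate. In 25 genes 1 library was at 0 while another was at 5 TPM or more, so such genes are described as listed at 0.

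The gene lists, tests, named-gene rule and most alternatives were fixed before the data were examined. There were 31 lists with 439 different genes. All 439 were found, 2 of them under an older name. The named genes are 33 key genes, the 4 members of each list with the highest mean TPM, members under 1 TPM in every library (all of them where these are 6 or fewer, otherwise 4 in list order), the 15 genes with the highest mean TPM, and the 10 genes with the largest ratio of highest to lowest library among genes with a mean TPM of at least 10. A few genes that this rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

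A gene was counted as detected at a TPM of at least 1 in all 3 libraries. Agreement between libraries was described by Pearson and Spearman correlation across genes with mean TPM of at least 1, on log2(TPM + 1). The astrocyte list was compared with 8 lists of other cell types on each gene's mean log2(TPM + 1), by a two-sided permutation test of list membership with 100000 resamples and Benjamini-Hochberg adjustment over the 8 comparisons. These 9 lists share no gene. The test treats genes as the units and genes are not independent replicates, so its p describes these lists in these libraries. Intervals of the differences come from 10000 bootstrap draws over genes and were added later. Differences are on the log2(TPM + 1) scale, which understates the difference of low genes.

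The position of each list was given as the percentile of its median among the medians of 10000 random lists of the same size drawn from protein-coding genes. The shift of a list in 1 library was its median difference from the mean of the other libraries, given as a percentile among 10000 random lists matched on mean expression in 20 bins. Values under 2.5 or over 97.5 are called outside the central range. Both are descriptions without a p-value.

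The procedures were tested on simulated data, 200 simulations each. Without a true difference the list comparison called 3.50% of simulated lists of the 18839 genes. A true difference of 2 on the log2 scale was called in 61.0% and one of 4 in 100%. These rates are for single comparisons, without the adjustment over 8 comparisons. The reported test adds that adjustment, and the lists set against the astrocyte list held 10 to 20 genes. The power of the reported test was not simulated and may be lower. Lists of 20 genes shifted by 0.1 in 1 library were outside the central range in 100% of simulations over 13946 genes, and unshifted lists in 5.00%. These simulations shuffled the differences over genes, which removes any joint variation of genes and any link between spread and level. The 5.00% was thus nearly fixed in advance and does not show how often real lists are called without a cause. The reported shifts used all 23583 names, with low genes, and lists of 8 to 22 genes. Random lists lay outside the central range of positions in 7.50% of simulations.

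Alternatives were pseudocounts of 0.1 and 0.01, detection limits of 0.5 and 5 TPM, FPKM in place of TPM, filters on low genes, the median over genes, the highest line per name, rescaling without ribosomal protein genes or by the upper quartile, and leaving out each replicate in turn. Values derived from the coverage column were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.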

Results

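Polyadenylated RNA was sequenced from HA1800 cells, human fetal cortical astrocytes in culture, in 3 libraries that form 1 group. The series concerns the conversion of such astrocytes into neurons by chemicals, and these libraries describe the starting cells. The question asked of them was which astrocyte, progenitor, neuron and other cell type genes the cells expressed, and which parts of the signalling pathways were present. The inferred depth was 82.6, 95.1 and 82.9 M reads for replicates 1, 2 and 3. Values are mean TPM ± SD over the 3 libraries (n = 3) unless a list median or a single library is named.

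The 15 genes with the highest mean TPM had varied functions. VIM, the intermediate filament protein vimentin, was highest at 12268 ± 464 TPM. It was followed by the actins ACTB at 8026 ± 168 and ACTG1 at 6997 ± 57.3, and by the glycolytic enzymes GAPDH at 7590.0 ± 320.3 and PKM at 4413 ± 101. The actin-binding thymosins TMSB10 and TMSB4X stood at 5639 ± 183 and 3710.0 ± 19.1, and the ferritin chains FTL and FTH1 at 5081 ± 108 and 3357 ± 43.5. CRABP1, a cytoplasmic retinoic acid-binding protein, reached 4139 ± 502 and TGFBI, a secreted protein induced by TGF-beta, 4036 ± 136. TPT1, RPL13AP5, EEF1A1 and RPL37A, of which EEF1A1 and RPL37A serve translation, completed the first 15 at 3861 ± 48.5, 3681 ± 444, 3578 ± 721 and 3289 ± 26.5.

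In all, 13637 genes were detected in all 3 libraries, of which 12525 were protein coding (66.5% of the protein-coding names) and 323 were long noncoding RNAs. Of these, 1869 stood at 100 TPM or more in all 3 libraries, and 5005 genes were listed at 0 in all of them. The first 10 genes took 6.23% ± 0.0827 of the total TPM, and ribosomal protein genes took 10.9% ± 0.0978.

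The 3 libraries resembled one another closely. Across 13946 genes, which are not independent replicates, Pearson's r was 0.993 for replicates 1 and 2, 0.992 for 1 and 3 and 0.990 for 2 and 3, with Spearman's rho of 0.994, 0.994 and 0.993. The median absolute log2 difference per gene was 0.07, 0.05 and 0.06 for the same pairs. The variance between libraries was 3.25, 1.96 and 2.99 times the approximate sampling noise over 4930 genes, so none was treated as a copy of another. This does not show whether they came from separate cultures. The highest library was at least 2 times the lowest in 365 genes (2.62%), and between single pairs of libraries in 210, 215 and 222 genes. Of the 365, 255 had a mean under 10 TPM, 199 were protein coding, 45 were small nucleolar RNAs and 42 were microRNAs.

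Among genes with a mean of at least 10 TPM, the 10 largest ratios included genes listed over the same stretch as another gene. Whether shared sequence caused the differences was not tested. RPL13A stood at 100.4 TPM in replicate 1, 616 in replicate 2 and 21.3 in replicate 3, and RPL13AP5, listed over the same stretch of chromosome 19, at 3684, 3236 and 4124. FAM45A stood at 2.40, 32.9 and 1.5 TPM and FAM45B, listed over nearly the same stretch of chromosome 10, at 33.9, 4.43 and 35.2. POLR2J3, RGPD5 and the read-through gene SERF2-C15ORF63 were listed at 0 in replicate 3 and at 42.3, 14 and 20.7 TPM in replicate 1. FAM133DP, LOC100093631, RPSAP58 and HNRNPA1L2 completed the group, each lowest in replicate 3.

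**Figure D1:**
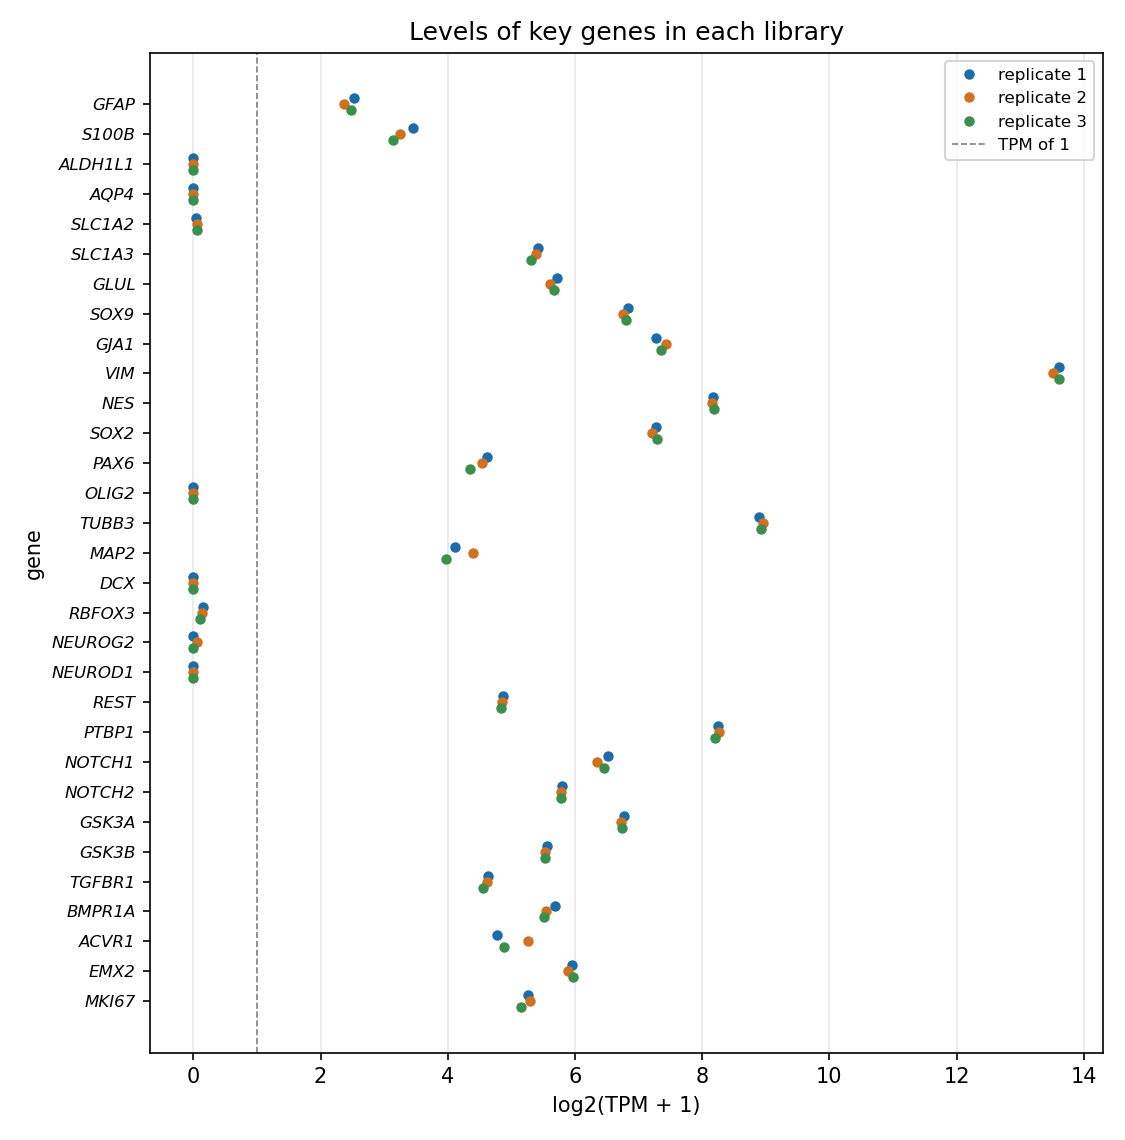
The log2(TPM + 1) of 31 key genes, one row per gene and one point per library (blue replicate 1, orange replicate 2, green replicate 3), with a dashed line at a TPM of 1. VIM lies furthest right with a mean of 12268 TPM, and ALDH1L1, AQP4, OLIG2, DCX and NEUROD1 are listed at 0 in all 3 libraries.

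Of the 20 astrocyte markers, 14 were detected, at widely different levels. CLU, which encodes the secreted chaperone clusterin, was highest at 1414 ± 73.0 TPM, followed by CST3 at 611 ± 8.46, the gap junction gene GJA1 at 162 ± 9.26 and the lipid carrier APOE at 162 ± 18.0. SOX9, a transcription factor of glial fate, was at 110.2 ± 3.11, the glutamate transporter SLC1A3 at 40.3 ± 1.66 and GLUL, glutamine synthetase, at 49.8 ± 1.96. GFAP, the astrocyte intermediate filament (chromosome 17, 42982994 to 42992920 on hg19, minus strand), was at 4.49 ± 0.308 and the calcium-binding protein S100B at 8.75 ± 1.06. The water channel gene AQP4 and the folate enzyme gene ALDH1L1 were listed at 0 in all 3 libraries. The glutamate transporter SLC1A2, the potassium channel KCNJ10, the connexin GJB6 and the gliogenic factor NFIA were at 0.0356, 0.0271, 0.142 and 0.635 TPM. The median of the list lay at percentile 53.9 of random lists of protein-coding genes, and at 7.95 when these were drawn from genes with a mean of at least 0.1 TPM. Here and below, that background leaves low genes out of the random lists only, which lowers percentiles by construction.

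Markers of radial glia and neural progenitors were detected in 12 of 15 cases, at percentile 84.3. Besides VIM, the extracellular matrix gene TNC stood at 302 ± 3.95 TPM, the progenitor filament NES at 287 ± 3.63 and the stem cell factor SOX2 at 152 ± 4.19. PAX6, a transcription factor of cortical progenitors, was at 21.7 ± 2.14. HES5 and FAM107A were at 0.251 and 0.214 TPM, and SOX1 stood at 0.00391, 0.690 and 0.330 in replicates 1, 2 and 3.

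Of 20 neuron markers 8 were detected, 4 of them at 100 TPM or more. The neurofilament genes NEFL and NEFM stood at 1521 ± 109 and 528 ± 25.7 TPM, the growth cone gene GAP43 at 152 ± 1.62 and the tubulin TUBB3 (chromosome 16, 89988417 to 90002505 on hg19) at 484 ± 9.50. For TUBB3 the value scaled from the coverage column was 85.3, which is 5.68 times lower. MAP2, a dendritic microtubule protein, was at 17.0 ± 2.75. The other detected markers, named after their values were seen, were SNAP25 at 21.6 ± 0.778 (8.44 from the coverage column), INA at 13.5 ± 1.84 and SYT1 at 7.78 ± 0.201. DCX, of migrating neurons, was listed at 0 in all 3 libraries, and RBFOX3, SYN1 and SYP stood at 0.0933, 0.523 and 0.609 TPM. The list lay at percentile 2.58, at 2.41, outside the central range, without replicate 3, and at 0 against genes with a mean of at least 0.1 TPM.

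Proneural transcription factors, several of which turn other cell types into neurons when forced, were near the floor. Only POU3F2, at 139.7 ± 2.78 TPM, and INSM1, at 5.64 ± 1.07, were detected among 15, and the list lay at percentile 0.0600. NEUROG1, NEUROG3 and NEUROD1 were listed at 0 in all 3 libraries, and NEUROG2 was at 0.0362 TPM in replicate 2 and listed at 0 in replicates 1 and 3. EOMES was at 0.219 TPM, and NEUROD2 at 0.0771, 0 and 0.0877 in replicates 1, 2 and 3. The genes that repress neuronal transcripts were all detected, 10 of 10, at percentile 99.9. PTBP1, a splicing repressor of neuronal exons, stood at 300.4 ± 5.97 TPM, the histone deacetylase HDAC1 at 190.2 ± 2.08, KDM1A at 168 ± 9.21 and CTDSP1 at 112 ± 9.64. REST, which silences neuronal genes outside neurons, was at 28.0 ± 0.282, the lowest mean of the 10. The housekeeping list lay at percentile 100, so a high percentile alone does not mark a state of repression.

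Genes of transmitter identity were detected in 2 of 12 cases, at percentile 0.390. These were the acetylcholine genes SLC18A3 at 15.7 ± 1.87 TPM and CHAT at 1.28 ± 0.227, while GAD1 and TH stood at 1.10 ± 0.286 and 0.817 ± 0.222. The glutamate transporter SLC17A6, the GABA genes GAD2 and SLC32A1 were listed at 0 in all 3 libraries, and SLC17A7 was at 0.0742 TPM in replicate 1 only. Of 18 transmitter receptors, 5 were detected (percentile 1.70), led by GABBR1 at 36.5 ± 1.80, GRIA1 at 34.6 ± 2.10, GRIN2A at 8.97 ± 0.214 and GRIA4 at 1.73 ± 0.180. GRIA2, GRIN1, GRIN2B and GRM3 were at 0.00826, 0.169, 0.0365 and 0.0317 TPM.

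Markers of other cell types the culture could hold were unevenly represented. Mural cell and fibroblast or meningeal genes were mostly detected, in 9 of 12 and 13 of 14 cases, at percentiles 95.9 and 84.6. TAGLN, an actin-binding protein of smooth muscle, stood at 996 ± 38.1 TPM, CNN1 at 141 ± 11.3, ACTA2 at 134 ± 19.6 and MCAM at 118 ± 3.75, while MYH11 was at 0.354 and ABCC9 was listed at 0 in all 3 libraries. COL1A1, a chain of type I collagen, stood at 1416 ± 95.2, FBLN1 at 407 ± 7.58, THY1 at 233 ± 9.32 and POSTN at 199 ± 28.8, with TBX15 at 0.129. COL1A2, which encodes the partner chain of type I collagen, was at 13.4 ± 1.13, 106 times lower than COL1A1.

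Oligodendrocyte lineage genes were detected in 5 of 14 cases (percentile 1.99), with CLDN11 at 277 ± 17.6 TPM, CNP at 126 ± 2.46, MBP at 31.0 ± 0.525 and CSPG4 at 17.8 ± 1.29. The lineage factors OLIG1, OLIG2 and NKX2-2 were listed at 0 in all 3 libraries and SOX10 was at 0.0542. Microglia genes were detected in 2 of 14 cases (percentile 0.0350), CD68, a lysosomal protein, at 22.4 ± 0.786 and TMEM119 at 1.86 ± 0.0738, with CSF1R at 1.12 ± 0.192 and LAPTM5 at 0.937 ± 0.184. AIF1, CX3CR1, P2RY12 and PTPRC were listed at 0 in all 3 libraries. Endothelial genes were detected in 2 of 12 cases (percentile 2.92), the VEGF receptor KDR at 104 ± 2.83 and EGFL7 at 48.1 ± 1.19, whereas TIE1, CDH5, VWF, CLDN5 and PECAM1 stood at 0.884, 0.881, 0.331, 0.157 and 0.0460. Of 10 ependyma and choroid plexus genes 7 were detected, all under 10 TPM (percentile 19.2), led by CLIC6 at 9.72 ± 0.184, CFAP126 at 8.34 ± 0.344, AQP1 at 7.94 ± 0.444 and FOLR1 at 7.78 ± 0.649. KL and DNAH9 were at 0.640 and 0.551, and TTR, the transthyretin made by the choroid plexus, was listed at 0 in all 3 libraries.

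**Figure D2:**
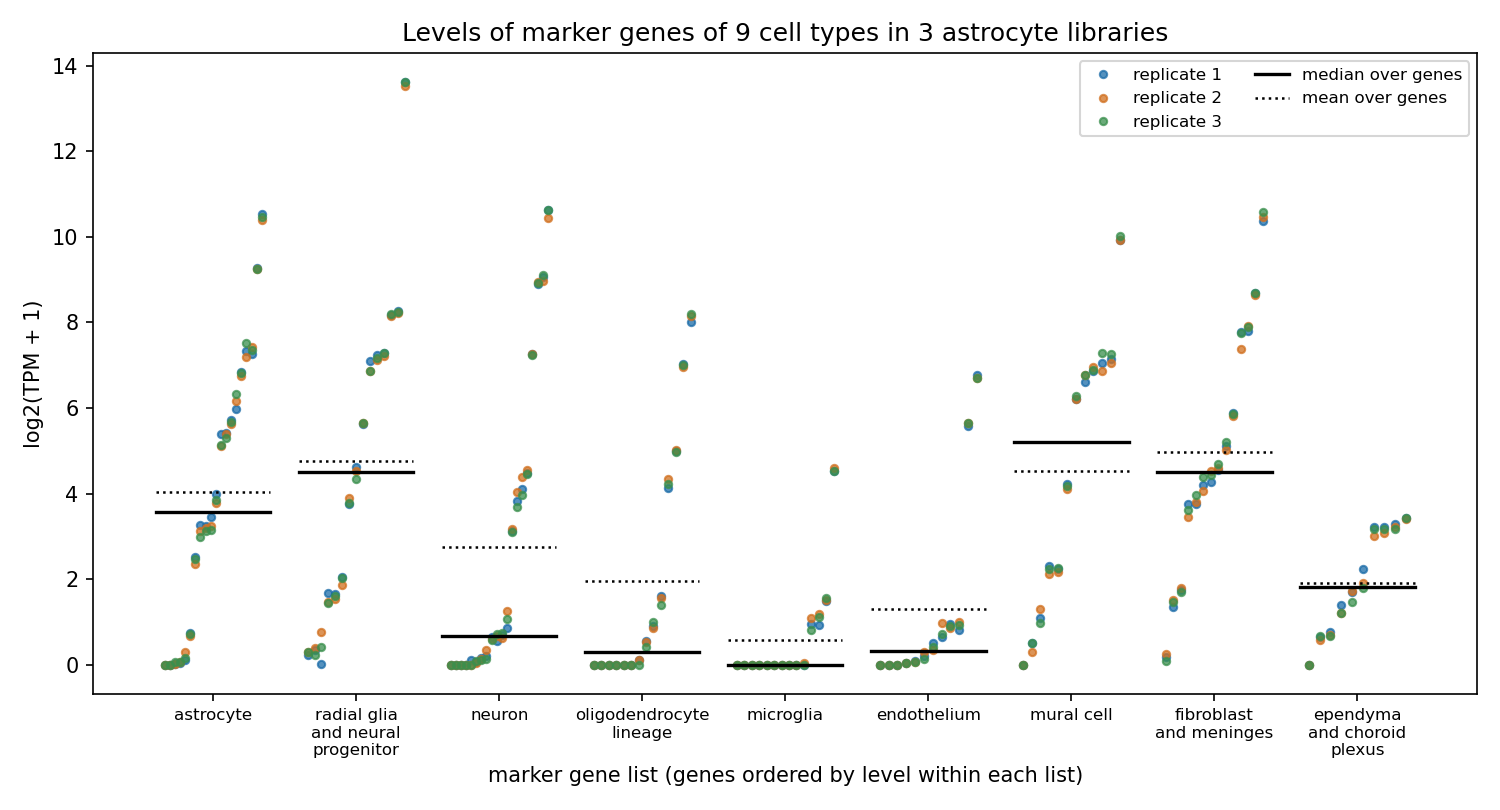
The log2(TPM + 1) of each marker gene of 9 cell types, one point per gene and library (blue replicate 1, orange replicate 2, green replicate 3), with genes ordered by level within a list, the solid line at the median and the dotted line at the mean over genes. The means run from 0.58 for microglia to 4.97 for fibroblasts and meninges, with astrocytes at 4.03.

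Of 8 tested comparisons, astrocyte markers exceeded 1 list, that of microglia. The comparisons thus do not establish that the cells were astrocytes, an identity taken here from the labels. The mean log2(TPM + 1) was 4.03 over the 20 astrocyte markers and 0.58 over the 14 microglia markers, a difference of 3.45 ± 0.05 (SD over 3 libraries) that was positive in 3 of 3 libraries (permutation p = 7.5e-04, Benjamini-Hochberg adjusted p = 0.00600). That call was lost with the median in place of the mean (adjusted permutation p = 0.205) and among members with a mean of at least 0.1 TPM (adjusted p = 0.165), where 4 microglia markers were left. Over all alternatives its adjusted p ran from 0.00312 to 0.205.

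Astrocyte markers were also higher than endothelial markers by 2.72 ± 0.04 (permutation p = 0.0177, adjusted p = 0.0706), ependymal markers by 2.11 ± 0.04 (adjusted p = 0.129 by the same test), oligodendrocyte markers by 2.07 ± 0.03 (adjusted p = 0.129) and neuron markers by 1.28 ± 0.05 (adjusted p = 0.386), in 3 of 3 libraries each, but none of these passed a threshold of 0.05. The endothelial comparison passed with values from the coverage column (adjusted permutation p = 0.0462), an alternative added after the data were seen, and its adjusted p ran from 0.0462 to 0.292 over all alternatives. The 95% bootstrap intervals over genes ran from 1.88 to 4.93 for microglia, 0.81 to 4.56 for endothelium, 0.50 to 3.70 for ependyma, 0.03 to 3.99 for the oligodendrocyte lineage and -0.80 to 3.31 for neuron markers. They thus lay above 0 for 3 lists whose adjusted p did not pass. Markers of mural cells, radial glia and fibroblasts were higher than those of astrocytes, with differences of -0.49 ± 0.04, -0.73 ± 0.02 and -0.95 ± 0.05 (astrocyte minus other) in 3 of 3 libraries and adjusted permutation p of 0.684, 0.622 and 0.516, none of which passed. Their intervals were -2.69 to 1.74, -3.13 to 1.6 and -2.93 to 1.10. The signs of these 3 differences turned among members with a mean of at least 0.1 TPM, to 0.10, 0.27 and 0.05.

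Genes of the pathways that conversion chemicals commonly act on were largely present. Of 22 Notch genes 18 were detected (percentile 91.2), with the gamma-secretase subunits NCSTN, PSENEN and APH1A at 177 ± 5.20, 139 ± 3.85 and 80 ± 2.21 TPM and the receptors NOTCH1 and NOTCH2 at 86.1 ± 5.34 and 54.2 ± 0.393. NOTCH4, HES5, HEYL and DLL4 were under 1 TPM in every library. Of 16 TGF-beta genes 15 were detected (percentile 85.3), with TGFB1 at 439 ± 12.2, TGFB2 at 84.4 ± 3.40, TGFBR2 at 43.4 ± 9.41 and the kinase receptor TGFBR1 at 23.2 ± 0.642, while the co-receptor TGFBR3 was at 0.0794. Of 18 BMP genes 15 were detected (percentile 79.0), led by the target genes ID3, ID1 and ID2 at 756 ± 64.0, 494 ± 10.5 and 129 ± 4.44, with SMAD1 at 56.5 ± 1.53 and the receptors BMPR1A and ACVR1 at 46.8 ± 3.19 and 30.8 ± 5.92. ACVRL1, BMP4 and BMP7 were under 1 TPM in every library.

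All 21 WNT and GSK3 genes were detected (percentile 93.9). CTNNB1, beta-catenin, stood at 474 ± 10.4 TPM, the secreted factors DKK3 and DKK1 at 435 ± 3.90 and 218 ± 3.29, and the kinases GSK3A and GSK3B at 106 ± 1.84 and 45.6 ± 0.647. Hedgehog genes were detected in 8 of 13 cases (percentile 44.8), with SMO at 73.0 ± 2.43, BOC at 59.7 ± 8.47, GLI3 at 32.6 ± 1.70 and SUFU at 25.9 ± 0.823. The ligand SHH was listed at 0 in all 3 libraries, and IHH and the pathway targets GLI1 and HHIP were at 0.148, 0.370 and 0.295. Retinoic acid genes were detected in 12 of 15 cases (percentile 97.8, and 89.9, inside the central range, against genes with a mean of at least 0.1 TPM), among them CRABP1, the retinol transporter STRA6 at 162 ± 14.9 and the enzyme ALDH1A3 at 76.6 ± 14.2. RXRG was listed at 0 in all 3 libraries, and ALDH1A2 and CYP26A1 were under 1 TPM in each. JAK-STAT genes were detected in 10 of 12 cases (percentile 97.5, 97.0 without replicate 2 or replicate 3 and 90.0 against that background), with OSMR at 105 ± 1.06, JAK1 at 83.9 ± 2.00, SOCS3 at 83.7 ± 2.41 and STAT3 at 70.2 ± 2.24, and with CNTF and CNTFR under 1 TPM in every library.

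Genes of reactive astrocytes, which change after injury or inflammation, varied widely within each list. Of 11 general reactive genes 7 were detected (percentile 14.7), with HSPB1 at 1185 ± 41.1 TPM, CD44 at 905 ± 3.78 and TIMP1 at 607 ± 10.5, while LCN2 was at 0.309 and STEAP4, CXCL10 and ASPG were listed at 0 in all 3 libraries. Of 8 genes linked to the inflammatory A1 state 6 were detected (percentile 65.8), with GBP2 at 109 ± 2.28, PSMB8 at 84.9 ± 0.973, AMIGO2 at 73.4 ± 6.81 and SERPING1 at 49.6 ± 1.83, and with SRGN and FBLN5 at 0.778 and 0.687. Of 12 genes linked to the A2 state 8 were detected (percentile 59.3), with S100A10 at 869.6 ± 25.2, EMP1 at 143 ± 10.9, TM4SF1 at 38.8 ± 3.82 and CLCF1 at 22.9 ± 0.850. PTGS2 was listed at 0 in all 3 libraries, and TGM1, CD14 and SLC10A6 were under 1 TPM in each.

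Both forebrain and more posterior genes were found. The forebrain factor LHX2 stood at 107 ± 2.65 TPM, EMX2 at 60.2 ± 1.91 and OTX1 at 44.5 ± 1.23. In all, 6 of 14 forebrain genes were detected (percentile 3.17), and EMX1, DLX1 and DLX2 were at 0.0874, 0.493 and 0.297, with OTX2 listed at 0 in all 3 libraries. Of 20 midbrain, hindbrain and spinal genes 6 were detected (percentile 0.130), and 5 of these were HOXB genes, which pattern the hindbrain and spinal cord. HOXB3 was at 211 ± 6.09, HOXB2 at 186 ± 1.69, HOXB4 at 148 ± 6.10 and HOXB5 at 128 ± 5.68, while EN1, EN2 and PAX5 were at 0.415, 0.0232 and 0.223 and PAX2 was listed at 0 in all 3 libraries.

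The cultures expressed cell division genes together with genes of growth arrest. All 22 proliferation genes were detected (percentile 99.8), with PCNA at 152 ± 5.86 TPM, UBE2C at 90.4 ± 7.98, TYMS at 87.6 ± 6.68, CCNB1 at 77.3 ± 6.21 and MKI67 at 36.7 ± 1.87. Of 16 senescence genes 14 were detected (percentile 99.99), with the cell cycle inhibitor CDKN1A at 587 ± 25.2 and the chemokine CCL2 at 362 ± 15.2, and with MMP3 at 0.0674. Cytokine and trophic factor genes were detected in 11 of 20 cases (percentile 8.03), led by the growth factor MDK at 1442 ± 45.5, then CCL2, PTN at 156 ± 3.25 and VEGFA at 56.3 ± 2.92. IL1B, CXCL1 and CXCL2 were at 0.252, 0.0595 and 0.331 and TNF was listed at 0 in all 3 libraries.

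As reference lists, all 12 housekeeping genes were detected (percentile 100), with RPLP0 at 2125 ± 175 TPM and B2M at 1492 ± 10.7 after ACTB and GAPDH. None of 8 haemoglobin-related genes was detected (percentile 0.260), and HBA1, HBA2, HBB and HBG1 were listed at 0 in all 3 libraries. Of 8 pluripotency genes 1 was detected (percentile 1.75), SALL4 at 1.12 ± 0.0690, with POU5F1 at 0.247, ZFP42 at 0.131, LIN28A at 0.0563, NANOG at 0.0161 and DPPA4 at 0.00973. Of the 31 lists, 6 lay above and 8 below the central range of random lists. Against genes with a mean of at least 0.1 TPM the radial glia, fibroblast and mural cell lists stayed inside it at 53.1, 52.97 and 85.5. The Notch, TGF-beta, BMP, WNT and hedgehog lists did so at 58.7, 50.4, 34.8, 68.7 and 8.5, and the A1 and A2 lists at 31.2 and 18.95. For 783 genes the TPM was more than 2 times the value from the coverage column, among them CDKN1A (188 from coverage), SMAD1 (5.49), EGFL7 (10.9), GRIA1 (14.2) and CHAT (0.629, under the detection limit). Which of the values is closer to the truth cannot be settled without the reads. GAPDH (4408), FBLN1 (233), CLDN11 (179), STRA6 (95.4), UBE2C (50.9) and FOLR1 (5.06) were also lower by that column, as was SLC1A2 (0.00784).

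Proliferation genes differed between the replicates as a group. In replicate 2 they were higher than in the mean of the other libraries in 22 of 22 genes, with a median log2 difference of 0.18 (percentile 100 of matched lists), and in replicate 3 they were lower in 22 of 22 genes, with a median of -0.15 (percentile 0). In replicate 1 the median was -0.01, with 10 genes higher and 12 lower. Senescence genes differed by 0.07 in replicate 2 (12 of 16 higher) and by -0.06 in replicate 1 (11 of 16 lower), TGF-beta genes by -0.08 in replicate 1 (12 of 16 lower) and cytokine genes by 0.07 in replicate 2 (15 of 20 higher). Mural cell genes differed by -0.06 in replicate 2 and 0.06 in replicate 3, fibroblast genes by 0.05 in replicate 3 and astrocyte genes by 0.04 in replicate 1. Housekeeping genes, a reference list, also differed, by 0.05 in replicate 2 (9 of 12 higher), as did A2 reactive genes, by -0.03 in replicate 1 and 0.06 in replicate 2, and general reactive genes, by -0.02 in replicate 1. In all, 14 of 93 list and library pairs lay outside the central range, where 4.65 would by chance. That number holds for genes that vary independently, which the genes of a list need not do. The 3 differences of a list are not independent, since each library is also part of the mean the others are set against.

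**Figure D3:**
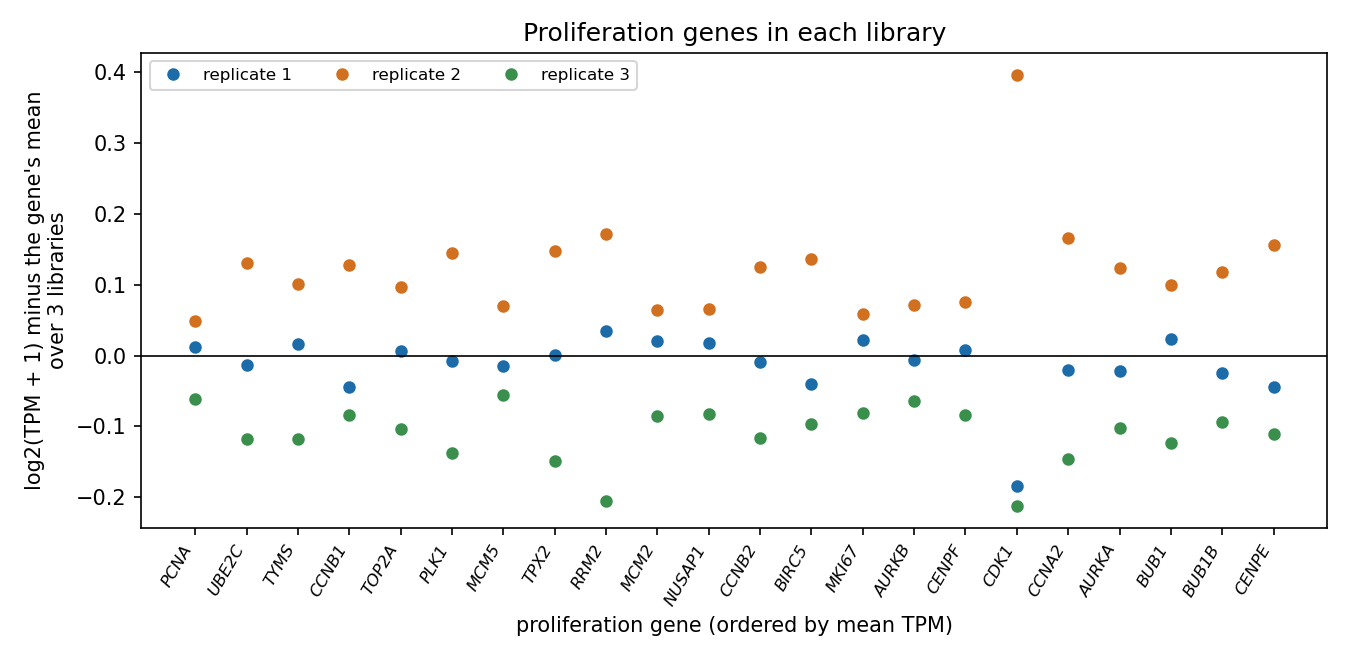
The log2(TPM + 1) of 22 proliferation genes minus each gene's mean over the 3 libraries, one column per gene and one point per library (blue replicate 1, orange replicate 2, green replicate 3). All 22 genes are above 0 in replicate 2 and below 0 in replicate 3.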

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

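Values from the coverage column were chosen only after the data had been seen, and the other alternatives were planned. Over the 8 list comparisons, the astrocyte markers exceeded the microglia markers by 2.74 to 6.94 on the log2 scale, and the call was lost among members with a mean of at least 0.1 TPM (3.00, adjusted permutation p = 0.165, with 16 and 4 genes left) and with the median over genes (3.58, adjusted permutation p = 0.205); the cause of the second loss was not tested. The endothelial difference passed with values from the coverage column (2.88, adjusted permutation p = 0.0462); the cause was not tested. The signs against radial glia, mural cell and fibroblast markers turned among members with a mean of at least 0.1 TPM, to 0.27, 0.10 and 0.053, where low astrocyte markers drop out by construction. The differences from neuron, oligodendrocyte and ependymal markers kept their sign and stayed short of the threshold in all 11 alternatives.

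The lowest Pearson correlation between libraries, 0.990, became 0.980 with a pseudocount of 0.1, 0.996 without a filter on low values and 0.993 with FPKM. FPKM differs from TPM by 1 constant per library, so this alternative amounts to a larger pseudocount on TPM. The causes of the changes were not tested further. Leaving out 1 replicate leaves a single pair, so the resulting 0.990 to 0.993 are the pairwise correlations already given. The number of genes detected ran from 11258 at 5 TPM to 14391 at 0.5 TPM, against 13637. The number of lists outside the central range of positions was 14, and 13 to 18 under the alternatives, with 18 for a background of genes with a mean of at least 0.1 TPM. Against that background the neuron, endothelium, ependyma, forebrain, cytokine and general reactive lists fell below the range and the retinoic acid and JAK-STAT lists came inside it. The filter was applied to the background and not to the list members. It can therefore only lower or keep a list's percentile, by construction. The number of shifts outside the range was 14, and 14 to 17 under the alternatives. The proliferation shifts in replicates 2 and 3 lay outside it in 5 of 5 alternatives, and those of mural genes in replicate 2 and general reactive genes in replicate 1 in 4 of 5. Rescaling a library moves a list and its matched random lists alike, so it could hardly change these outcomes. The filter at 1 TPM removed no proliferation gene, since their lowest mean was 9.65 TPM. Among the values of single lists and key genes, 450 stayed within their spread or on their side of the range and 33 moved. The 33 include VIM, SOX9, GJA1, NES and SOX2, which moved only with values from the coverage column. In each of these genes TPM was 0.904 times that value, so their moves reflect a common scale factor. Many of the 450 could not move or could hardly move. Leaving out 1 replicate cannot shift a key gene's mean by its SD. A pseudocount of 0.1 or FPKM hardly changes the order of genes on which the positions rest. The 450 are therefore no measure of robustness. Depth limits values near 0.0321 TPM, what 1 read over 1 kb was worth in replicate 1.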

Other observations

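All tests of explanations below were chosen after the values were seen, as were the genes named for the first time here. These explanations are technical ones, cells of another type in the culture included. The design has 1 group, so no biological explanation was tested.

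Genes outside the fixed lists, and 1 within them, chosen with no test, stood at widely different levels. The keratins KRT8, KRT18 and KRT19, which form the filaments of simple epithelia, stood at 523 ± 11.4, 723 ± 18.4 and 679 ± 31.8 TPM, each over 100 times the level of GFAP. The imprinted genes MEST and MEG3 were at 590.2 ± 23.7 and 238 ± 29.8, while IGF2 and H19 were at 4.18 ± 0.107 and 4.29 ± 0.325. The RNA-binding proteins IGF2BP2 and IGF2BP3 were at 71.9 ± 0.785 and 52.6 ± 0.761, while IGF2BP1 was at 2.30 ± 0.124 and LIN28B at 0.0240. The chromatin proteins HMGA1 and HMGA2 were at 775 ± 114 and 4.88 ± 0.710. SOST, an inhibitor of WNT signalling known from bone, was at 576 ± 38.0, and the adhesion genes CDH2 and CDH1 were at 602 ± 15.7 and 1.51 ± 0.226. By the coverage column MEST, MEG3 and HMGA1 were lower, at 247, 76.1 and 438. Of the fixed senescence list, CDKN2A, a cell cycle inhibitor that accumulates in aged cultures, was at 103 ± 21.9 (64.4 by the coverage column). Outside the lists, RB1 was at 58.9 ± 1.23, while TERT was at 0.0160 in replicate 1 and listed at 0 in replicates 2 and 3.

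HOXB genes were expressed beside forebrain genes: 8 of 10 HOXB genes on chromosome 17 were detected, among them HOXB6 at 227 ± 9.09, HOXB7 at 75.4 ± 1.26, HOXB8 at 238 ± 9.18 and HOXB9 at 7.88 ± 0.121 TPM, with LHX2 at 107 and EMX2 at 60.2. If hindbrain or spinal cord cells in the culture were the source, HOXA, HOXC and HOXD genes would be expected too, but 0 of 29 were detected and the highest stood at 0.0141, against a median of 166.6 for the detected HOXB genes, which argues against it. Reads of 1 gene shared with overlapping HOXB genes are argued against by 6 detected HOXB genes that overlap no other listed gene. Cells of another origin that use this cluster alone, or opening of the cluster in culture, may account for the pattern and remain untested. Bulk libraries do not show whether forebrain and HOXB transcripts came from the same cells.

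The 4 neuron markers at 100 TPM or more had a median of 506 TPM. Neurons in the culture are argued against as the source of this level, since STMN2 and SNAP25, abundant in such cells, averaged 1.62% of the mean of the 4 (0.171 and 21.6 TPM). The other detected markers, SNAP25, MAP2, INA and SYT1, stood at 7.78 to 21.6 TPM, and their source was not tested. By the coverage column SNAP25 was at 8.44. The lowest of the 4 by that column, TUBB3, stood at 85.3, under the limit of 100 TPM. Summing of transcript isoforms into the gene value may thus account for the place of TUBB3 among the 4. As the whole cause of the levels it is argued against, since all 4 stood at 85.3 or more by that column. Expression of these cytoskeletal genes by progenitor-like or cultured glial cells may account for the pattern, a hypothesis with no test here.

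Among fibroblast and meningeal genes, COL1A1, FBLN1, THY1 and POSTN stood at 1416, 407, 233 and 199 TPM. Fibroblasts are argued against as the source of these levels, since COL1A2, COL3A1 and DCN, abundant in such cells, averaged 2.49% of the mean of the 4 (13.4, 17.5 and 11.3 TPM, with DCN at 1.77 by the coverage column). FN1, SPARC, COL6A2 and COL6A1, which fibroblasts also hold in abundance but share with many cultured cells, stood at 2648, 1844, 1500 and 1115 TPM, so the argument rests on the 3 low genes. For the 7 other genes of the list a small share of fibroblasts cannot be told apart from expression by the cells labelled astrocytes. The reason is that COL1A2, COL3A1 and DCN averaged 69.4% of the median of those 7, 20.3 TPM. Also, no library of sorted cells was analysed here.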
